A study of Mus musculus with 2 samples.

How the data were processed

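Heart tissue of male B6CASTF1/J mice aged 14 days was profiled by long-read RNA sequencing in 2 libraries, which the labels call biological replicates 1 and 2 of 1 group. Both carry the same donor label, and the labels mention 3 males for each tissue sample without saying whether tissue was pooled, so SDs measure the spread between these 2 samples, which may be partly technical. The labels give the tissue samples different numbers, yet the description of both libraries names the same tissue sample and the same 2 cDNAs. The p-values of the exact tests rest on counting error alone and hold no spread between samples. Per the labels, each library started from 2 µg of total RNA, and Lexogen set 4 and Ambion mix 1 spike-ins were used. The values are counts of reads per transcript model, per the file headers, and were deposited by the authors as whole numbers without normalization. Models are listed from 1 count upward. The deposited annotation holds the GENCODE M21 genes on the mm10 assembly, per the files' notes, with the models of each library that were not in the reference, which carry the source name TALON. The aligner, the version of the annotation tool, the filters on models and the sequencing instrument are not given in the sources used here. The novelty class of each model (Known, ISM, NIC, NNC, Genomic, Antisense, Intergenic) is the authors' own, per the file headers.

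Each model's count was added to its gene. Reference genes held 1059016 counts in replicate 1 and 1064679 in replicate 2, and these totals set the scale for CPM, so that 1 count was worth 0.944 and 0.939 CPM and a floor of 3 counts 2.83 and 2.82 CPM. Models on new genes, which name no reference gene, held 2.68% and 2.89% of all counts, and spike-ins 1.72% and 1.25%, and both were left out of the totals and tests. Only spike-ins with ERCC names carried counts. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Intervals of shares are exact Clopper-Pearson intervals at 95%. A fold against 0 counts was computed against a floor of 3 counts per library and is given as a lower bound.

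The design, the gene lists, the pairs, the rule for named genes and 45 alternative settings were fixed before the data were examined. With 1 group no comparison of conditions exists, and each test compares these 2 libraries, not conditions. Each gene with a summed count of at least 10 was tested by a two-sided exact conditional binomial test of its counts against the library totals, with Benjamini-Hochberg adjustment over 10162 genes and a threshold of 0.05, and then once more over each list alone. Log2 ratios are of replicate 2 over replicate 1 on CPM plus a pseudocount of 1. A list with at least 5 tested members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these libraries and is not a p-value. The share of the first member of each of 37 pairs was compared between libraries by Fisher's exact test, adjusted over the pairs. The dominant annotated transcript of each gene was compared with the gene's other annotated transcripts by a two-sided Fisher's exact test in 2633 genes with at least 20 such counts in each library. The biological coefficient of variation is the square root of edgeR's common dispersion in an intercept-only design with TMM scaling. New multi-exon models were matched between the libraries by chromosome, strand and every intron, because the names of new models are set library by library. In the length classes a gene has the length of its dominant annotated transcript, unless its longest one is named.

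By rule the text names the 20 genes with the highest mean CPM, the 4 highest detected members of each list (all detected ones in the sex list), the 10 genes with the largest log2 ratio in each direction among those past the threshold, and all pairs with enough counts. It also names up to 20 genes of the isoform list with the highest counts, the 10 genes with the smallest p in the isoform test, and the 10 most abundant multi-exon new models found in both libraries, at most 1 per gene. Some items that these rules select are not reported here. Members named because they are the only ones past the threshold, and the genes that share intron chains with the extremes, were chosen after their values were seen. The same holds for the long genes Ttn, Ryr2 and Fn1 in the account of read length. The fixed lists were 17 gene lists (sarcomere, calcium handling, ion channels and gap junctions, fatty acid oxidation, glycolysis, tricarboxylic acid cycle, nuclear oxidative phosphorylation, mitochondrially encoded, cytosolic ribosome, extracellular matrix, cell cycle, cardiac transcription factors, natriuretic and stress, imprinted, sex, long noncoding RNA, immune and interferon). A further 17 marker lists covered cardiomyocyte, fibroblast, endothelial, smooth muscle and pericyte, endocardial, epicardial, macrophage, lymphocyte, erythroid, Schwann and neural, adipocyte, atrial, conduction, skeletal muscle, thymus, lung and liver. After the library test had been seen, 4 marker lists (second atrial, second thymus, second fat, ventricular) and 2 alternatives that remove a trend on transcript length were added. That trend is a lowess curve, fraction 0.3, of the log2 ratio on the length of the dominant annotated transcript over genes with a summed count of at least 100, and 95.6% of tested genes have such a length.

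The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 (size factors only). All 21988 detected reference transcripts had the introns of GENCODE M21, and gene positions are those of M21. Of the 55536 gene lines deposited, 39540 had the same start and end as M21, so the deposited gene ends were not used. The tests were checked on simulated counts with known changes. For the library, isoform and length checks these counts held counting error alone, with no spread between libraries. Their numbers of unchanged genes called are therefore not error rates for these data. The library test recovered 51% of 2-fold changes (87.3% where the summed count was at least 100) and 88% of 4-fold changes, and called 17 unchanged genes among 10103. The isoform test recovered 3% of 2-fold and 27% of 4-fold changes of the odds among 2633 genes and called 1 unchanged gene. A simulated coefficient of 0.2 was estimated as 0.203. With a simulated length trend over 10166 genes, removal of the trend lowered the calls among unchanged genes from 508 to 7 and kept 100% of changed genes. The alternatives changed the scaling (TMM, DESeq2 size factors, totals without mitochondrially encoded genes), the minimum count (1 or 50), the pseudocount (0.5 or 5), the transcripts counted (those with a reference identifier only), the test (edgeR's exact test with a common dispersion, a chi-square test), the minimum for isoforms (10 or 50), the minimum count of a model (2 or 5), the matching of models (splice sites within 10 bases) and the library used (each one left out). Counts of the parental alleles need the reads and were not analysed here.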

Results

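The data are long-read RNA sequencing libraries made from the hearts of male mice aged 14 days. The animals were of the B6CASTF1/J strain, the first-generation cross of C57BL/6J with the wild-derived CAST strain. The series holds 1 group with 2 libraries, named replicate 1 and replicate 2 by the labels, so the questions it can answer are what the heart transcriptome holds at this age and how far the libraries differ. Replicate 1 held 1107678 counts and replicate 2 held 1110707, of which 1059016 (95.6%) and 1064679 (95.9%) fell on genes of the reference annotation. A reference gene was detected in either library in 16269 cases and in both in 13169. A further 1371 genes had counts in replicate 1 only and 1729 in replicate 2 only, and the median count of a detected gene was 13 and 14. Protein-coding genes took 98.2% ± 0.053 (SD, n = 2) of the counts on reference genes, processed pseudogenes 1.03% ± 0.029, antisense genes 0.185% and long intergenic noncoding RNA 0.176%.

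The highest gene was Slc25a4 (ENSMUSG00000031633.4, chromosome 8, 46206797 to 46211284), the ADP/ATP carrier of the mitochondrial inner membrane, at 24544.5 ± 1765 CPM (counts scaled to the library total, mean ± SD, n = 2 for all such values). Myh6 (ENSMUSG00000040752.16, chromosome 14, 54941921 to 54966927), the alpha myosin heavy chain, reached 21987 ± 1625 CPM, and tropomyosin Tpm1 17667 ± 63.9 CPM. Next came the muscle creatine kinase Ckm at 11784 ± 185 CPM, the ATP synthase subunit Atp5b at 10132.5 ± 59.5 CPM and the fatty acid binding protein Fabp3 at 9583 ± 745 CPM. The light chain Myl3 (7803 ± 217 CPM), Atp5a1 (7671 ± 388 CPM), the globin Hba-a1 (7406 ± 1738 CPM), troponin C Tnnc1 (7400.3 ± 764 CPM) and the cytochrome c oxidase subunit Cox4i1 (7032 ± 1865 CPM) followed. Among the rest of the 20 highest genes were Uqcrc1 (6957 ± 464 CPM), the calcium pump Atp2a2 (6739 ± 971 CPM), cardiac actin Actc1 (6515 ± 284 CPM), Aldoa (6029 ± 208.5 CPM), Hadhb (4691 ± 29.7 CPM), Eno3 (4506 ± 16.3 CPM), Hbb-bs (4401 ± 882 CPM) and Actn2 (3549 ± 4.06 CPM). On transcripts with a reference identifier alone the order changed, with Myh6 at 12581 CPM below Tpm1 (21472 CPM) and Ckm (14177 CPM). Together the 20 highest genes of each library held 18.3% and 17.7% of its counts.

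**Figure D1:**
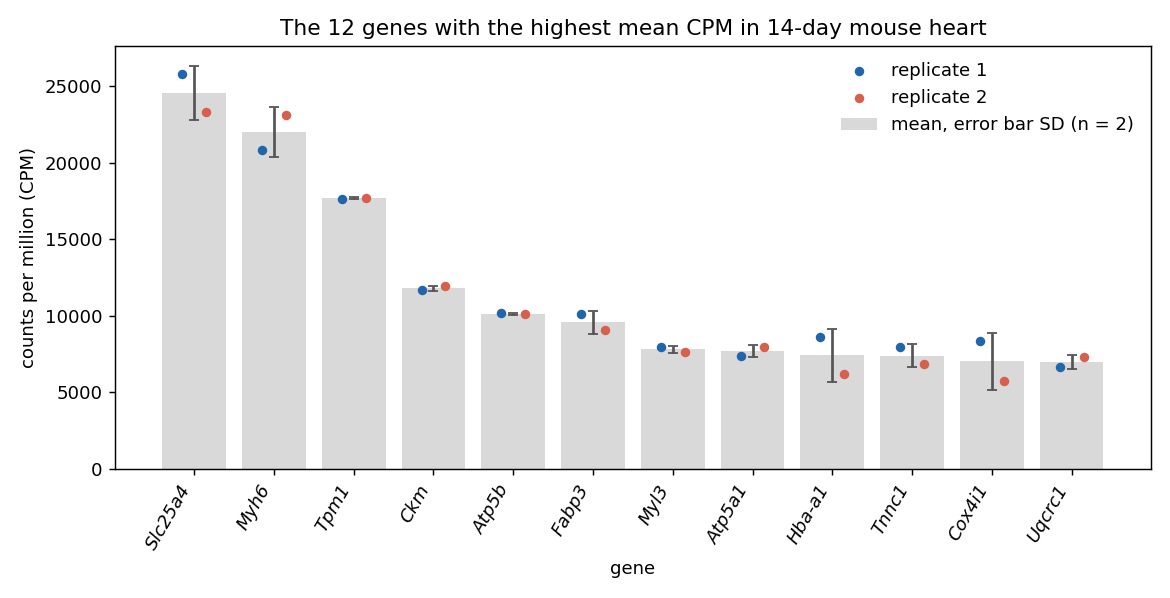
CPM of the 12 genes with the highest mean, with 1 point per library and a bar at the mean. Slc25a4 and Myh6 lead at 24544.5 and 21987 CPM, and Hba-a1 and Cox4i1 have the points farthest apart for their level.

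Sarcomere genes took 8.46% ± 0.033 of the counts, and all 40 listed members were detected. Calcium handling genes took 1.73% ± 0.056, led by Atp2a2, its inhibitor Pln (2564 ± 383 CPM), Srl (1798 ± 156 CPM, but 367 CPM on transcripts with a reference identifier alone) and the calcium store protein Casq2 (1395 ± 44.7 CPM). Ion channels and gap junctions took 0.381% ± 0.0077, led by connexin 43, Gja1 (926.8 ± 194 CPM), Fxyd1 (790.7 ± 287 CPM), Kcnk3 (418 ± 60.4 CPM) and Atp1b1 (362 ± 23.9 CPM). Between the libraries, 7 sarcomere genes were past the threshold in each direction (10 higher in replicate 1 and 8 higher in replicate 2 when adjusted over the list alone), and 26 of 40 did not pass. Myh6 was higher in replicate 2 (log2 ratio 0.15) and Tnnc1 in replicate 1 (log2 ratio -0.21), with adjusted p of 1.4e-26 and 2.4e-17 in the exact binomial test. After removal of a trend on transcript length both lay near 0 (-0.01 and 0.05) and did not pass. In edgeR's exact test with the common dispersion neither passed (adjusted p 1), nor did Pln, Atp2a2, Fxyd1 or Gja1. In the calcium list 4 genes were higher in replicate 1 and 3 in replicate 2, the same numbers as when adjusted over the list alone. Pln lay at a log2 ratio of -0.31 and Atp2a2 at 0.29, but on transcripts with a reference identifier alone Pln lay at -0.09 and did not pass. Of the channel genes Fxyd1 was higher in replicate 1 (-0.76) and Gja1 in replicate 2 (0.43), with 1 and 3 in the respective directions when adjusted over the list alone. Without the length trend Gja1 (0.33) stayed past the threshold and Fxyd1 (-0.07) did not.

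Of the genes of energy metabolism, nuclear-encoded subunits of oxidative phosphorylation took 10.4% ± 1.12 of the counts, fatty acid oxidation 3.90% ± 0.021, the tricarboxylic acid cycle 3.49% ± 0.085 and glycolysis 2.49% ± 0.035. Fatty acid oxidation was led by Fabp3, Hadhb, Acadvl (3282 ± 16.3 CPM) and Acaa2 (2928 ± 51.7 CPM), and glycolysis by Aldoa, Eno3, Ldha (3198 ± 244 CPM) and Ldhb (2807 ± 157 CPM). Cycle genes with high levels included Mdh2 (3019 ± 27.4 CPM), Idh2 (2839.7 ± 87.2 CPM) and Mdh1 (2803 ± 63.3 CPM). Between the libraries, 1 fatty acid oxidation gene was higher in replicate 1 and 3 in replicate 2 (1 and 4 adjusted over the list alone). Glycolysis had 1 gene in each direction (2 and 5 adjusted over the list alone), with Ldha at a log2 ratio of 0.16, which under TMM scaling was 0.07 and did not pass. The cycle had 3 genes higher in replicate 2 and 0 in replicate 1 (4 and 0 adjusted over the list alone).

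Genes of oxidative phosphorylation differed between the libraries as a group. Of 78 tested nuclear-encoded members, 50 were higher in replicate 1, 3 in replicate 2 and 25 did not pass (61 and 6 adjusted over the list alone), and the summed share was 11.2% in replicate 1 and 9.63% in replicate 2. The median log2 ratio of the list was -0.40, below all 10000 random lists matched on expression. Cox4i1 (ENSMUSG00000031818.12, chromosome 8, 120668222 to 120674207) lay at -0.55 (adjusted p 3.3e-113, exact binomial test), whereas Atp5a1 (0.10) and Uqcrc1 (0.14) were higher in replicate 2. Under TMM scaling Atp5a1 and Uqcrc1 lay at 0.02 and 0.05 and did not pass, and in edgeR's exact test none of the 3 passed (adjusted p 1). The dominant transcripts of the list were short, with a median of 745 bases. With a trend on transcript length removed, 21 members were higher in replicate 1 and 1 in replicate 2, and the median was -0.14. Mitochondrially encoded genes took 0.280% ± 0.074 of the deposited counts on reference genes. How reads were aligned and filtered before that is not given, so this share is not a measure of mitochondrial RNA in the tissue. Of 11 tested mitochondrially encoded genes 5 were higher in replicate 1 and 0 in replicate 2 (10 and 0 adjusted over the list alone). They were led by mt-Co1 (1526 ± 278 CPM, log2 ratio -0.37), mt-Cytb (494 ± 200 CPM, -0.85), mt-Nd5 (160 ± 33.2 CPM, not past the threshold) and mt-Nd1 (157 ± 55.2 CPM, -0.73). Their median log2 ratio was -0.75, their median dominant length was 1038 bases, and 4 of 11 were past the threshold after the length trend was removed. Cytosolic ribosomal protein genes took 1.31% ± 0.178, with 14 of 77 higher in replicate 1 and 1 in replicate 2 (22 and 1 adjusted over the list alone). Their median length was 799 bases, and after removal of the length trend 4 and 1 members passed and the median moved from -0.28 to -0.07. Of its abundant members Rplp0 (951 ± 27.6 CPM) and Rpl3 (625 ± 9.02 CPM) did not pass.

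**Figure D2:**
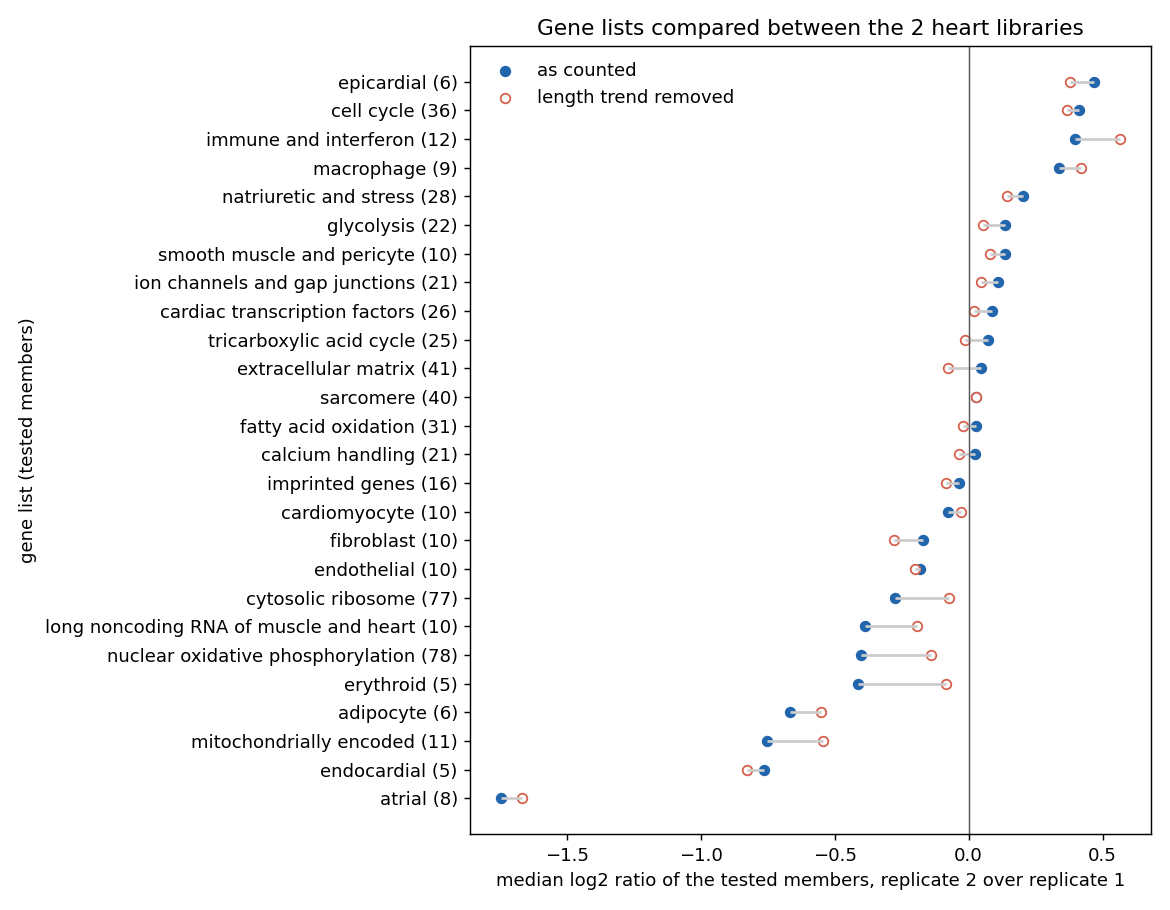
Median log2 ratio of replicate 2 over replicate 1 for each gene list with at least 5 tested members, before and after removal of the trend on transcript length. The atrial list (-1.74), the mitochondrially encoded list (-0.75) and the nuclear oxidative phosphorylation list (-0.40) lie on the side of replicate 1, and the cell cycle list (0.41) on that of replicate 2.

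Extracellular matrix genes took 1.08% ± 0.018 of the counts, led by Col3a1 (3502 ± 167 CPM), Sparc (1322 ± 31.0 CPM), Col4a2 (740.3 ± 57.4 CPM) and Col4a1 (693 ± 82.0 CPM). On transcripts with a reference identifier alone Col4a2 and Col4a1 were at 149 and 309 CPM. Of 41 tested members 2 were higher in replicate 1 and 1, Col4a1 (log2 ratio 0.24), in replicate 2 (2 and 3 adjusted over the list alone). Under TMM scaling Col4a1 lay at 0.16 and did not pass. Cell cycle genes took 0.116% ± 0.020, led by Ccnd3 (171 ± 22.7 CPM), H2afz (132 ± 7.49 CPM), Cdkn1c (112 ± 10.9 CPM) and Cdk4 (90.9 ± 11.0 CPM). No cell cycle gene passed the test between the libraries, over all genes or adjusted over the list alone, but the list's median log2 ratio of 0.41 lay above 99.97% of the random lists. Cardiac transcription factors took 0.134% ± 0.0064, led by Esrra (188 ± 43.3 CPM), Nkx2-5 (187 ± 0.039 CPM), Klf15 (130.4 ± 25.5 CPM) and Gata4 (128 ± 16.2 CPM). Esrra was the only one past the threshold (log2 ratio -0.47, higher in replicate 1), also when adjusted over the list alone. On transcripts with a reference identifier alone it had 48.5 CPM, below Nkx2-5 (226 CPM), and its log2 ratio was 0.31 and did not pass. Natriuretic peptide and stress genes took 0.637% ± 0.155, with Nppa at 2191 ± 1918 CPM, Jund at 868 ± 88.6 CPM, skeletal actin Acta1 at 659 ± 99.4 CPM and Hspb8 at 634 ± 70.2 CPM. In that list 1 gene, Nppa, was higher in replicate 1 and 2 genes, Acta1 among them (0.31), in replicate 2 (2 and 4 adjusted over the list alone). Under TMM scaling Acta1 lay at 0.22 and did not pass.

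Imprinted genes took 0.291% ± 0.0078, led by Gnas (1301 ± 24.2 CPM), Dcn (692 ± 67.2 CPM), Snrpn (369 ± 10.6 CPM) and Mest (125 ± 17.8 CPM), and 0 of 16 tested members differed between the libraries, over all genes or adjusted over the list alone. Of the list of sex-linked genes, the Y-linked Eif2s3y (94 and 93 counts), Ddx3y (46 and 59), Uty (11 and 26) and Kdm5d (3 and 3) were detected and the other 6, Xist among them, were not. The list took 0.0158% ± 0.0017, and 0 of its 3 tested members passed. Long noncoding RNA of muscle and heart took 0.0349% ± 0.0047, led by 1810058I24Rik (112.5 ± 5.09 CPM), Mhrt (61 and 46 counts), Gm15543 (61 and 30) and H19 (43 and 32). Gm15543 was higher in replicate 1 (log2 ratio -1.01), alone among 10 tested members and also when adjusted over the list alone, but not without a minimum count, on transcripts with a reference identifier alone (-0.96) or with the length trend removed (-0.46). Immune and interferon genes took 0.0584% ± 0.0124, led by H2-D1 (290.5 ± 38.2 CPM), Cxcl12 (70.1 ± 12.4 CPM), Cd74 (58.4 ± 18.4 CPM) and B2m (48.0 ± 10.5 CPM). Of 12 tested members 1 was higher in replicate 2 and 0 in replicate 1 (2 and 0 adjusted over the list alone), and the list's median log2 ratio was 0.40.

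The markers of the cell types of the heart wall were detected except for 1 epicardial gene. Cardiomyocyte markers took 4.59% ± 0.094 of the counts, fibroblast markers 0.716% ± 0.023, endothelial markers 0.151% ± 0.0105, and smooth muscle and pericyte markers 0.102% ± 0.0078. Endocardial markers took 0.0150% ± 0.0019, epicardial markers 0.0141% ± 0.0017 and macrophage markers 0.0376% ± 0.0082. Of 10 cardiomyocyte markers 3 were higher in replicate 1 and 2, Myh6 and Actc1, in replicate 2 (4 and 2 adjusted over the list alone). Under TMM scaling Actc1 lay at 0.01 and did not pass. The fibroblast marker Gsn (1843 ± 309 CPM) was higher in replicate 1 at a log2 ratio of -0.34, and the other 9, among them Col3a1, Dcn and Col1a1 (585 ± 55.1 CPM), did not pass (4 and 2 adjusted over the list alone). Of the endothelial markers Cav1 (335 ± 12.05 CPM), Cldn5 (279 ± 8.27 CPM), Fabp4 (272 ± 73.6 CPM) and Egfl7 (194 ± 28.7 CPM), Fabp4 was higher in replicate 1 (-0.56), the only 1 of 10, also when adjusted over the list alone, and 0 of 10 passed with the length trend removed. Smooth muscle and pericyte markers were led by Rgs5 (399 ± 45.8 CPM), Acta2 (331 ± 44.0 CPM), Kcnj8 (119 ± 15.1 CPM) and Abcc9 (47.5 ± 15.1 CPM), and 0 of 10 passed, over all genes or adjusted over the list alone. The endocardial markers Tmem100 (59 and 78 counts), Plvap (75 and 44), Cytl1 (18 and 7) and Nfatc1 (13 and 11) did not pass, although 1 endocardial marker was higher in replicate 1 when adjusted over the list alone. The median log2 ratio of the 5 tested endocardial markers was -0.76, below all but 0.115% of matched random lists, and -0.83 with the length trend removed. The epicardial markers Upk3b (47 and 61 counts), Msln (54 and 50), Wt1 (15 and 15) and Upk1b (11 and 17) did not pass either, nor did any when adjusted over the list alone. Of 9 tested macrophage markers Lyz2 was higher in replicate 2 (131 ± 56.1 CPM, log2 ratio 0.89), also when adjusted over the list alone, and C1qa (65.0 ± 10.4 CPM), C1qb (53.7 ± 13.1 CPM) and C1qc (57.9 ± 0.884 CPM) did not pass.

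Red blood cell markers took 1.503% ± 0.315, nearly all of it globin. Hba-a1, Hbb-bs, Hba-a2 (1982 ± 432 CPM) and Hbb-bt (711 ± 91.2 CPM) were all higher in replicate 1, at log2 ratios of -0.48, -0.41, -0.45 and -0.26 (4 and 0 of 5 tested, also when adjusted over the list alone). The median dominant length of the list was 699 bases, and 1 member, Hba-a1, stayed past the threshold after the length trend was removed. The paired alpha and beta globin genes are near copies, so the division of counts within each pair is uncertain. Schwann and neural markers took 0.00334% ± 0.00061, with Cnp at 26 and 20 counts, Mbp at 6 and 7 and Sox10 at 2 and 1. Conduction system markers took 0.002685% ± 0.00034, with Gja5 at 19 and 15 counts, Hcn4 at 4 and 2 and Tbx3 at 3 and 3. Neither list had a member past the threshold, over all genes or adjusted over the list alone. The skeletal muscle list took 1.24% ± 0.029, nearly all of it Ckm, which heart muscle also expresses. Its member Acta1 passed, also when adjusted over the list alone, while Tnni2 had 3 and 6 counts and Mylpf 0 and 3, and the other 6 had 0.

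Among the fixed lists with at least 5 tested members the atrial list had the median log2 ratio farthest from 0. The 8 atrial markers took 0.508% of the counts of replicate 1 (95% Clopper-Pearson interval 0.495 to 0.522) and 0.129% of those of replicate 2 (0.122 to 0.136). Of 8 tested members 6 were higher in replicate 1 and 0 in replicate 2 (8 and 0 adjusted over the list alone). The peptide hormone gene Nppa (ENSMUSG00000041616.9, chromosome 4, 148000722 to 148002079) had 3757 and 889 counts, 4.25-fold more by CPM in replicate 1 (counting interval 3.95 to 4.58). The atrial light chains Myl7 (602 and 161 counts, log2 ratio -1.90) and Myl4 (586 and 182, -1.69) and the calcium pump regulator Sln (209 and 46, -2.17) lay on the same side, with adjusted p of 7.6e-58, 1.7e-47 and 1.9e-23 in the exact binomial test. The median log2 ratio of the list was -1.74, and -1.67 after removal of the length trend. Adipocyte markers took 0.0418% ± 0.0136, with 3 of 6 tested higher in replicate 1 and 0 in replicate 2 (4 and 0 adjusted over the list alone). Ucp1, the uncoupling protein of brown fat, had 32 and 2 counts, a ratio of 16.1 (counting interval 4.10 to 138.5). Cidea had 120 and 70 counts (log2 ratio -0.78), Fabp4 343 and 234, and Cfd 23 and 23. On transcripts with a reference identifier alone Fabp4 (-0.53) and Cidea (-0.76) did not pass, nor with the length trend removed (-0.40 and -0.71). Thymus markers had 14 counts in replicate 1 and 83 in replicate 2, and 3 of 4 tested, Cd8a, Cd8b1 and Dntt, were higher in replicate 2 (0 and 3 adjusted over the list alone), while Cd1d1 (14 and 10 counts) did not pass. The lymphocyte list had 7 and 27 counts, led by Cd3d (1 and 11), Trbc1 (0 and 9), Cd79b (3 and 1) and Cd79a (2 and 1). None of it passed over all genes, and 1 member was higher in replicate 2 when adjusted over the list alone. Of the 6 lung markers 0 were detected, which allows a share of up to 0.000283% and 0.000282% at 3 counts. Of the 6 liver markers Apoa2 had 1 and 1 counts and Ttr 0 and 1.

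Across all genes, 331 of 10162 tested differed between the libraries, 168 higher in replicate 1 and 163 higher in replicate 2. With TMM scaling 334 differed, 243 higher in replicate 1 and 91 in replicate 2, which moved the share higher in replicate 2 from 49.2% to 27.2%. DESeq2 size factors gave 196 and 123, or 38.6%. The median absolute log2 ratio of the 331 genes was 0.61, and 78 differed by over 2-fold, 23 of them higher in replicate 1 and 55 in replicate 2. Across genes Pearson's r of log2 CPM was 0.952 and Spearman's rho 0.947, although genes are not independent replicates. The chi-square statistic per degree of freedom was 2.59, where counting error alone gives 1, and the biological coefficient of variation was 0.124. With this common dispersion in edgeR's exact test 22 genes differed, 11 in each direction. Of the 53 named genes past the main threshold 14 passed that test, namely Nppa, Sln, Myl7, Myl4, Ucp1, Tmem163, Usp50, Gm28035, Gm6969, Lck, Cd8a, Cd8b1, Prss16 and Gm10774. The other 39, among them Cox4i1, Hba-a1, Myh6, Dntt and Ikzf1, did not. The log2 ratio followed transcript length across 3390 genes (Spearman's rho 0.363), and 160 of the 331 genes stayed past the threshold once that trend was removed, among 201 then found.

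Of the 10 genes farthest toward replicate 2, 7 are known from T cells or the thymus. Lck (ENSMUSG00000000409.14, chromosome 4, 129548344 to 129573641), a kinase of T cell receptor signalling, had 0 and 44 counts, at least 14.6-fold higher in replicate 2 (adjusted p 2.6e-11, exact binomial test). The co-receptor genes Cd8a (0 and 26) and Cd8b1 (0 and 25) were at least 8.62-fold and 8.29-fold higher. Prss16, a thymus protease (0 and 18, at least 5.97-fold), Ikzf1 and Dntt (each 0 and 14, at least 4.64-fold) and Tbata (0 and 12, at least 3.98-fold) followed, with Plaur (0 and 15, at least 4.97-fold). Toward replicate 1 lay Nppa, Sln, Ucp1, Tmem163 (37 and 7 counts, ratio 5.31, interval 2.34 to 14.1) and Fmo2 (13 and 1, ratio 13.1, interval 1.96 to 555.4). Without the minimum count, or on transcripts with a reference identifier alone, Fmo2 did not pass. Only 3 of the 14 counts of Ikzf1 and 1 of the 12 of Tbata were on annotated transcripts, so both rest mostly on unannotated models. For the remaining 7 of the 20 extremes the assignment of reads to the gene is uncertain. Usp50 had 123 and 0 counts, at least 41.2-fold more in replicate 1, of which 120 fell on a single-exon model (chromosome 2, 126709096 to 126709354) that ends where the pseudogene Gm10774 (3 and 78 counts, ratio 25.9 toward replicate 2, interval 8.53 to 128.1) begins. Gm6969 (54 and 1 counts, ratio 54.3, interval 9.34 to 2184) likewise abuts an unannotated model on chromosome 12. Gm28035 (39 and 0 counts, at least 13.1-fold) shared intron chains holding 25 of its counts with models named Phyhd1 in replicate 2, and Iqschfp (18 and 2, ratio 9.05, interval 2.17 to 80.4) shared chains with Schip1. Gm49329 (0 and 13, at least 4.31-fold) shared chains with Gm49326, and Gm20521 (11 and 0, at least 3.69-fold), like Usp50, Gm28035, Iqschfp and Gm49329, had 0 counts on annotated transcripts.

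**Figure D3:**
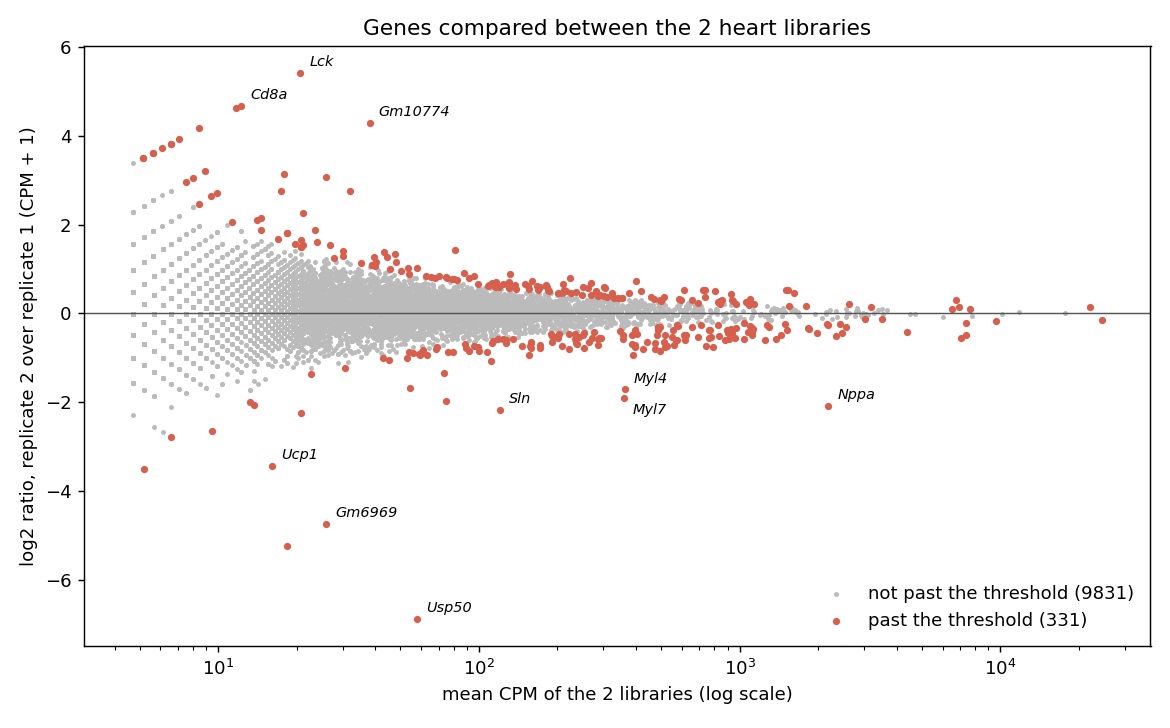
Log2 ratio of replicate 2 over replicate 1 against mean CPM (log axis) for the 10162 tested genes, with the 331 past the threshold in colour. Nppa stands apart at high expression toward replicate 1 (-2.09), and Lck and Cd8a mark the low-count edge toward replicate 2.

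The heart or muscle form led most of the fixed pairs of related genes. In 30 of 37 pairs the first member, which is in general that form, held over 50% of the pair's counts in both libraries, and in 22 of them over 90%. Myh6 made up 99.9% ± 0.011 of Myh6 and Myh7, troponin I Tnni3 92.1% ± 0.088 against the fetal Tnni1, Actc1 90.8% ± 0.896 against Acta1, and troponin T Tnnt2 90.4% ± 3.82 against Tnnt1. Only 7.47% and 7.71% of the counts of Tnni3 (37 and 28) were on annotated transcripts, all of them retained-intron forms. Its share thus rests mostly on unannotated models. Tnnt2 had 249 and 215 counts, with under 20 on annotated transcripts in at least 1 library. Atp2a2, Ryr2, Tnnc1, Kcnip2, Mybpc3, Myoz2 and Tpm1 made up 99.8% or more in each library against Atp2a1, Ryr1, Tnnc2, Kcnip1, Mybpc1, Myoz1 and Tpm2, and Casq2 98.7% ± 0.046 against Casq1. Of the metabolic pairs Ckm made up 97.7% ± 0.270 (against Ckb), Cpt1b 95.9% ± 1.09 (Cpt1a), the insulin-responsive glucose transporter Slc2a4 95.4% ± 0.537 (Slc2a1), Eno3 93.3% ± 0.656 (Eno1), Slc25a4 91.9% ± 0.305 (Slc25a5) and Pdk4 91.9% ± 0.464 (Pdk1). Gja1 made up 98.2% ± 0.647 (Gja5), Cacna1c 92.5% ± 0.896 (Cacna1h) and Hcn2 91.6% ± 3.36 (Hcn4). The second member led in 7 pairs. Among these, Ldhb held 46.8% ± 0.509 against Ldha, Hk2 45.9% ± 1.67 against Hk1, Acadl 43.1% ± 0.260 against Acadm, Myom2 43.0% ± 5.69 against Myom1, Pygm 37.6% ± 0.745 against Pygb and Cox7a1 29.2% ± 4.07 against Cox7a2. On transcripts with a reference identifier alone Myom2 led its pair, with a share of 53.6%, and the share of Hk2 was 25.04%. Intermediate shares were those of Cox6a2 (83.7% ± 0.533, Cox6a1), Atp5g1 (65.5% ± 1.48, Atp5g3), Pfkm (58.6% ± 2.96, Pfkl), Cox8b (54.9% ± 4.95, Cox8a) and Pgam2 (83.7% ± 4.18, Pgam1).

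In 9 of the 37 pairs the share differed between the libraries by Fisher's exact test after adjustment over the pairs. The atrial light chains gave the smallest p. Myl2 held 80.6% of Myl2 and Myl7 in replicate 1 and 92.9% in replicate 2 (adjusted p 1.6e-38, Fisher's exact test), and Myl3 held 93.5% and 97.8% against Myl4 (5.1e-44). Nppa held 99.0% and 96.5% against Nppb (1.1e-05), and Fabp3 96.9% and 97.6% against Fabp4 (0.00797). Pgam2 held 86.6% and 80.7% against Pgam1 (0.000261), Cox7a1 32.1% and 26.4% against Cox7a2 (0.00235), Myom2 47.0% and 39.0% against Myom1 (0.00854), Cox8b 58.4% and 51.4% against Cox8a (0.00971), and Actc1 91.5% and 90.2% against Acta1 (0.0289).

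Among 2633 genes with at least 2 annotated transcripts detected, the dominant transcript held a median of 93.7% of the counts on annotated transcripts, with 1459 genes at 90% or more and 72 under 50% in both libraries. Of the 79 genes of the fixed isoform list 35 had enough counts. Of the counts on annotated transcripts Tpm1-205 held 99.3% ± 0.054 and Actn2-201 99.6% ± 0.209, and Tpm4-201 and Des-201 were at 100% in both libraries. Pkm-202, which carries the upstream of a pair of exclusive exons (chromosome 9, 59675029 to 59675195), held 93.5% ± 0.943, and Pkm-201, with the downstream exon (59675568 to 59675734), 6.48%. Slc25a3, the mitochondrial phosphate carrier, also has exclusive exons, and Slc25a3-206 (chromosome 10, 91122207 to 91122331) held 93.9% ± 1.15 against 4.98% ± 1.20 for Slc25a3-201 (91121922 to 91122043). Atp2a2-202 (chromosome 5, 122453514 to 122501895), with the distal last exon, held 97.54% ± 0.134 and Atp2a2-201 2.31%. Ldb3-203, the short form that ends in its own last exon (chromosome 14, 34561272 to 34561881), held 88.6% ± 1.5, and Ldb3-201 9.80% ± 0.172. These shares are of the counts on annotated transcripts, and of all counts of their gene Ldb3-203 held 44.1%, Actn2-201 59.1%, Pln-201 53.0% and Hnrnpa2b1-204 30.4%. Trdn-208 held 58.4% ± 4.00, Trdn-202 25.2% and Trdn-204 16.0%, and Asph-206 held 75.2% ± 6.65, Asph-208 9.25% and Asph-201 7.10%.

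Of the other genes of the isoform list, some were divided between forms that differ by an exon. Gnas-208, with an exon at chromosome 2, 174336747 to 174336791, held 53.1% ± 0.030, and Gnas-207 and Gnas-206, without it, 30.0% and 16.6%. Vegfa-202 held 50.8% ± 2.48, and Vegfa-207, which adds an exon at chromosome 17, 46022277 to 46022348, 39.7% ± 1.06. Vegfb-202 held 60.7% ± 3.58 and Vegfb-201, with as many exons, 39.3%. Hnrnpa2b1-204 held 65.4% ± 3.68, and Hnrnpa2b1-210, which lacks an exon at chromosome 6, 51464428 to 51464547, 22.9% ± 6.48. Ndufv3-202 held 95.2% ± 1.43 and Ndufv3-201, with an added exon at chromosome 17, 31527310 to 31528401, 4.82%. Atp5c1-201 held 97.46% ± 0.048 and Atp5c1-203, with an added exon at chromosome 2, 10056770 to 10056806, 2.54%. Acadm-201 held 99.7% ± 0.290, Cryab-201 97.7% ± 0.753 and Pln-201 91.05% ± 0.603, and Hspb7-201 was at 100% in both libraries. Between the libraries 1 of 2633 genes passed in the choice of transcript, with 86 at an unadjusted p under 0.05. Cox4i1-204 held 63.0% of the annotated counts of Cox4i1 in replicate 1 and 57.7% in replicate 2 (adjusted p 2.7e-07, Fisher's exact test). The next were Plpp1-202 (77.3% and 56.9%, adjusted p 0.139, Fisher's exact test), Myh6-201 (76.7% and 78.8%), Ddx5-201 (83.8% and 74.9%) and Hadhb-201 (54.1% and 57.6%). Dpf2-202 (77.6% and 56.5%), Csnk1a1-204 (59.3% and 43.6%), Asb2-201 (64.0% and 70.9%), Fxyd1-213 (65.2% and 56.7%) and Pea15a-201 (92.2% and 80.1%) complete the 10 smallest, and none of these 9 passed. A chi-square test over all transcripts of a gene found 2 of 1570, Cox4i1 and Csnk1a1. On simulated data the main test recovered 27% of 4-fold changes of the odds among 2633 genes, so smaller shifts were mostly not detectable at this depth.

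Most reads matched annotated transcripts in full. Models with all junctions of an annotated transcript (Known) held 78.3% ± 0.309 of the counts without spike-ins and made up 19.7% ± 0.38 of the models. Incomplete splice matches (ISM), which lack junctions at an end, held 8.29% ± 0.146, models with new combinations of known splice sites (NIC) 4.95% ± 0.254 and models with a new splice site (NNC) 3.10% ± 0.137. Models of the class Genomic, with 98.3% and 98.1% of their counts on single-exon models, held 2.69% ± 0.088, antisense models 2.41% ± 0.127 and intergenic models 0.292% ± 0.024. Of the NNC models 82.7% had a single count, as had 78.8% of intergenic and 25.3% of Known models. Of the counts of Hba-a1 99.7% were on Known models, of Tpm1 97.9%, of Ckm 96.9%, of Atp2a2 73.5%, of Actn2 59.4% and of Myh6 46.0%. Of the ISM counts 77.4% ± 1.11 kept the 3' end and 5.53% the 5' end.

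The long genes of the heart were seen in part. Genes whose dominant transcript is over 4 kb had 17.7% ± 0.358 of their counts on ISM models and 61.4% ± 0.541 on Known ones, against 5.03% ± 0.194 and 90.35% ± 0.252 for genes under 1 kb. Titin, Ttn, had 107 and 94 counts and its longest model spanned 7978 and 11690 bases of 106824, and none of its counts were Known. The ryanodine receptor Ryr2 had 81 and 76 counts with longest models of 9299 and 8352 of 16814 bases. For fibronectin Fn1 the longest model had the full 8315 bases in both libraries, which is the length of a model, not of reads. Known models held 26.5% and 25.4% of the counts of Fn1, and the median model length was 4252 and 4873 bases. Genes under 1 kb took 18.1% of the counts in replicate 1 and 14.4% in replicate 2, and those over 4 kb 12.2% and 13.7%. The median model length over counts was 1833 and 1925 bases (1879 ± 65.1).

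**Figure D4:**
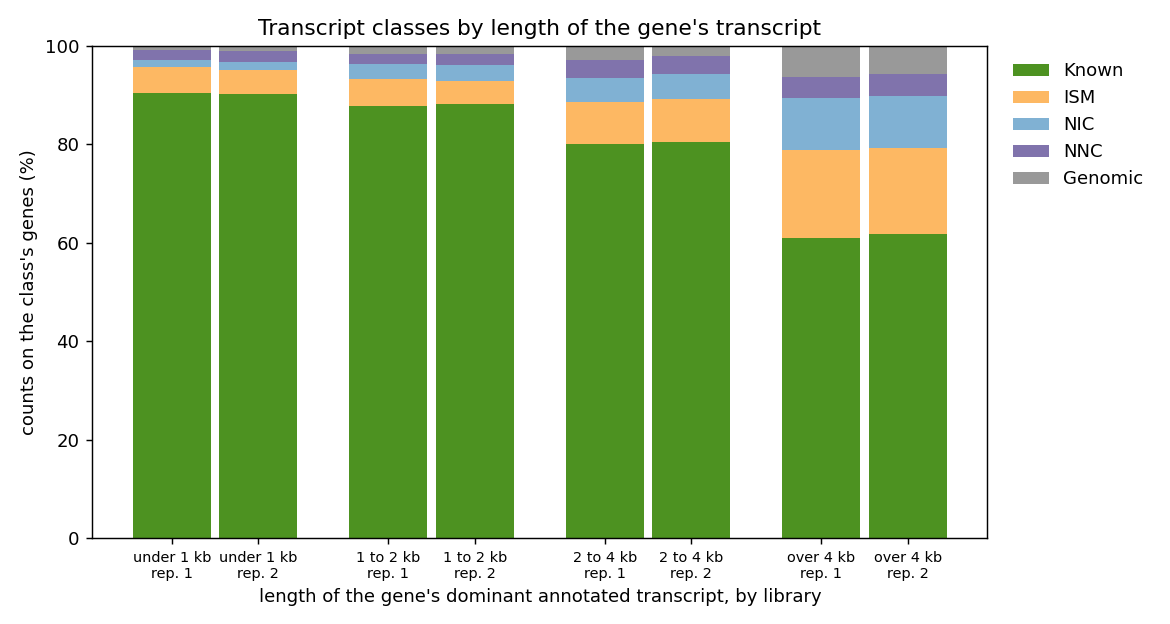
Share of counts (percent) per novelty class in genes grouped by the length of their dominant annotated transcript, with 1 stacked bar per library. Known models fall from 90.35% under 1 kb to 61.4% over 4 kb as the mean of the libraries, and incomplete splice matches stand at 5.03% and 17.7%.

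Unannotated spliced models with several reads were found again in the other library. Of all multi-exon models without a reference identifier 35.9% ± 1.80 had the same intron chain in the other library, from 21.8% ± 1.68 of those with 1 count to 64.6% ± 2.1 with 2 to 4, 96.1% ± 0.917 with 5 to 9 and 99.9% ± 0.0027 with 10 or more. By class the share was 44.5% for ISM, 39.6% for NIC and 22.9% for NNC. Both libraries shared 20443 such chains, and 1413 of them had at least 10 counts in each. The most abundant was a Myh6 NIC model of 39 exons with 3437 and 3935 counts, 15.8% ± 0.283 of the gene. In it the 3' end of an intron, on the minus strand, lies at 54942005 in place of 54942002 on chromosome 14. In Oaz1, the antizyme whose translation uses a ribosomal frameshift, 96.8% ± 0.309 of the counts (3040 and 3062) were on a NIC model that lacks the annotated 4-base intron at chromosome 10, 80828292 to 80828295. An Atp5f1 ISM model without the first annotated intron (chromosome 3, 105959559 to 105959925) held 96.0% ± 0.347. Srl had 67.5% ± 1.80 on a NIC model with an intron boundary moved by 3 bases (chromosome 16, 4493881 in place of 4493878), and Idh3b 82.3% ± 0.742 on a NIC model (130279438 in place of 130279727, chromosome 2). A further 4 were ISM models, in Ndufa4 (50.01% ± 0.424), Atp5j (74.6% ± 1.2), Actn2 (32.3% ± 6.0) and Atp5b (17.75% ± 4.61, 2264 and 1557 counts).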

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

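The removal of the length trend, the second atrial list and the test of the atrial genes after length correction were chosen only after the library comparison had been seen. The series has 1 group, so no biological explanation was tested, and other tissue in a sample is weighed as a technical one.

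Counts outside the reference genes are sums over many models. Each listed model has at least 1 count, so these sums exceed the floor of 3 counts by construction, and that comparison tests nothing. ERCC spike-ins held 19022 counts in replicate 1 and 13891 in replicate 2, and all 14 of the spike-ins with at least 100 counts were higher in replicate 1. New genes antisense to annotated ones held 26144 and 28532 counts, and new genes between annotated ones 3496 and 3605. The most abundant model between genes lay on chromosome 11, 31545928 to 31549643, with 2 exons and 301 and 425 counts.

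The 331 genes that differed between the libraries included many with short transcripts and most of the atrial markers. The log2 ratio followed transcript length (Spearman's rho 0.363). With that trend removed, 160 of the 331 (48.3%) stayed past the threshold, under the bound of 50% set for length as the source. With the genes that passed only after removal there were 201, or 60.7% as many, between that bound and the 80% set against it. The bounds did not say whether such new genes count, so how much of the pattern length accounts for stays open. Length is argued against for the atrial genes, because the median log2 ratio of their 8 markers, Nppa and Myl7 among them, stayed at -1.67 after the correction. More atrial tissue in replicate 1 may be the source, and a second list of 10 tested atrial genes had a median log2 ratio of -0.26, below all but 0.61% of matched random lists yet short of the bound of -0.5. In that list 12 of 18 detected members were higher in replicate 1 and 6 in replicate 2, with 751 and 592 counts in sum. Mybphl (127 and 32 counts, log2 ratio -1.96) was past the threshold while Kcna5 (51 and 71) and Chrm2 (55 and 52) were not. The list's genes are also expressed outside the atria to a degree not analysed here, so more atrial tissue as an explanation stays open too.

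Models on new antisense genes held 2.36% and 2.57% of all counts, spike-ins included, and 95.9% and 95.7% of the counts opposite a detected gene were on single-exon models. If they were reverse copies of abundant sense transcripts, their counts would follow those of the genes opposite. Across 8541 models in replicate 1 Spearman's rho was 0.0988, and 0.112 in replicate 2, neither at least 0.3 in both libraries nor under 0.1 in both, the bounds set beforehand. Across all 16269 detected genes, those without antisense counts included, rho was higher, 0.256 and 0.273, a measure for which no bound had been set, so copying cannot be told apart from other sources at this spread. The most abundant antisense model (chromosome 17, 39843013 to 39846245, 1498 and 2002 counts) lay opposite Gm26917, which had 3 counts in replicate 1.

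Incomplete splice matches were more frequent in longer transcripts. Their share was 12.7 percentage points higher (SD 0.164) in genes over 4 kb than in genes under 1 kb, and in the long genes 82.0% of these counts kept the 3' end. Both are what reads that stop before the 5' end of long transcripts would give, so such reads may be a source of this class. In genes under 1 kb, however, 73.0% ± 6.49 of these counts also kept the 3' end. The number of introns per gene, which sets how many junctions a read can lose, was not accounted for. True short forms, such as that of Actn2 with many reads in both libraries, are not excluded, since other explanations were not tested.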

How the results depend on the processing

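The 2 settings that remove the length trend were chosen only after the data had been seen, and the 45 others were planned. No result past the threshold in the main setting changed direction in an alternative where it passed. Between alternatives Atp5b (-0.10 with TMM, 0.11 on reference identifiers), Myl3 (-0.14 with TMM, 0.08 without the length trend) and Tpm1 (-0.08 and 0.05 in these), not past the main threshold, passed in opposite directions. Leaving out 1 of the 2 libraries moves a mean by less than 1 SD by construction, so it tests nothing here. No paired analysis was possible because the series has 1 group. For the genes that differ between the libraries, TMM scaling gave 91 higher in replicate 2 in place of 163. edgeR's exact test with the common dispersion gave 22 genes (11 and 11), all of them among the 331, and its dispersion was estimated from the same 2 libraries, so that it takes their whole difference as spread. Removal of the length trend gave 201 (96 and 105). Here and below the cause was not tested unless the setting itself shows it. The coefficient of variation of 0.124 became 0.125 with no minimum count, 0.1205 with a minimum of 50, 0.1244 on transcripts with a reference identifier only and 0.1238 with total counts. On transcripts with a reference identifier only, shares moved to 7.96% (sarcomere), 1.45% (calcium handling), 0.371% (ion channels), 4.43% (fatty acid oxidation), 2.82% (glycolysis), 3.75% (tricarboxylic acid cycle), 0.904% (extracellular matrix), 0.0854% (transcription factors), 0.323% (imprinted) and 0.0137% (sex). For genes grouped by their longest annotated transcript, the share of 1 to 2 kb moved from 27.8% to 30.3% in that setting. That of over 4 kb fell from 20.3% to 15.9%. Some list medians crossed the percentile bounds set for them. Glycolysis lay at 0.13 (percentile 98.7) with a minimum of 50, and the noncoding list at -0.049 with no minimum and -0.19 without the length trend, inside the bounds. The immune list lay at 0.37 with a pseudocount of 5, 0.40 (98.7) with a minimum of 50 and 0.56 without the length trend. The chi-square test of isoforms gave 2 genes. With all transcripts in the denominator the median dominant share was 76.4%. Among models with at least 2 or 5 counts, Known held 82.1% or 85.4%, ISM 7.23% or 6.06%, NIC 4.18% or 3.55%, NNC 1.84% or 1.33%, Genomic 2.47% or 2.04%, antisense 1.98% or 1.48% and intergenic 0.190% or 0.136%. The share of new models found again became 43.1% with splice sites within 10 bases and 73.7% for models with at least 2 counts. Of 138 named genes 29 had levels over 1.5-fold lower on transcripts with a reference identifier only, and 0 over 1.5-fold higher. Of the values of single genes, pairs and marker lists, with the settings that leave out a library not counted, 1122 kept their side of the threshold or stayed within the spread, 167 moved by more than the spread, 30 passed only in the alternative and 80 passed only in the main setting, of which edgeR's exact test took 39. Depth limits genes with few counts, since 51% of simulated 2-fold changes were found over all genes and 87.3% where the summed count was at least 100.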

Other observations

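The thymus and fat tests, the ventricular list and the genes named outside the fixed rule were chosen only after the data had been seen.

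In some genes, in addition to those already named, most counts were on an unannotated model found in both libraries. Recurrence alone cannot tell a true splice form from an error made alike in both libraries, and this was not tested. These genes were chosen after their values were seen. In Phb2, an inner membrane scaffold protein, 97.4% of the counts were on a model that lacks an annotated exon of 6 bases (chromosome 6, 124716425 to 124716430). Idh3g, a subunit of isocitrate dehydrogenase, had 89.4% on a model without an annotated exon of 12 bases (chromosome X, 73782298 to 73782309) and with an intron boundary moved by 4 bases. Oaz2 had 89.8% on a model without its annotated 4-base intron (chromosome 9, 65686269 to 65686272), as did Oaz1. The models of Oaz1 and Oaz2 hold 0 introns that the closest annotated transcript lacks. They differ from it by that 4-base intron and are not evidence of a new splice form. Vdac3 had 88.55% on a model with 700 and 746 counts whose splice site was moved by 4 bases, and Tmed2 72.2% on another form. By contrast, in Atp2a2 a model without an exon of 18 bases (chromosome 5, 122500931 to 122500948), with an intron boundary likewise moved by 4 bases, held 6.21% ± 0.25.

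Single-exon reads of the same genes were given different classes in the libraries. In Pln, 1375 counts (45.8% of the gene) were classed Genomic in replicate 1 and 909 (37.2%) were classed ISM in replicate 2. In Slc25a4 2301 counts (8.42%) were ISM in replicate 1 and 1928 (7.77%) Genomic in replicate 2. Hspb7 had 73 ISM counts (17.4%) in replicate 1 and 72 Genomic counts (21.3%) in replicate 2. Among 34623 intron chains shared by the libraries, 1434 (4.14%) were classed differently, and 52 of 34380 on reference genes carried another gene's name.

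A hypothesis for the T cell genes higher in replicate 2 is that its tissue held some thymus, which lies on the heart. A second list of T cell and thymus genes, none of them in the first lists or among the extremes, had 33 counts in replicate 1 and 252 in replicate 2, 7.60-fold higher (interval 5.27 to 11.3, p 7.4e-43, exact binomial test), and 22 of 24 detected members were higher there. Satb1 (5 and 50 counts), Coro1a (7 and 38), Tcf7 (3 and 35) and Lat (1 and 18) passed the threshold. Of the 24 members 13 also had a count in replicate 1. This is consistent with thymus tissue in replicate 2, although T cells of another origin would raise most of these genes too. The dissection is not described in the sources used here.

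A second hypothesis, for Ucp1, Cidea and Fabp4, is brown fat in replicate 1. A second list of fat genes had 345 and 334 counts, 1.04-fold higher in replicate 1 (interval 0.891 to 1.21, p 0.645, exact binomial test), short of the 1.5-fold set as its sign. By the bound first set, a ratio under 1.1-fold would have counted against fat. The demand that the interval also lie below that bound was added after this value had been seen. A small amount of fat is not excluded, since the list's genes are also expressed in heart to a degree not analysed here. The median log2 ratio of its 10 tested members was -0.24, below all but 1.95% of matched random lists, and 11 of 17 detected members were higher in replicate 1. Its most abundant members were Thrsp (78 and 66 counts), Gpd1 (72 and 61) and Acly (47 and 86), the last higher in replicate 2. As a counterpart to the atrial genes, a list of ventricular genes had 4336 and 4554 counts, 1.04-fold higher in replicate 2 (p 0.0396, exact binomial test). Its members did not move together, with Myl2 higher in replicate 1 (log2 ratio -0.26) and Fhl2 (0.46) and Ankrd23 (0.61) in replicate 2.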
